A study of Caenorhabditis elegans with 2 samples.

How the data were processed

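The series measured where a tagged MADF-5 protein lay on the genome of Caenorhabditis elegans by chromatin immunoprecipitation followed by sequencing. Per the labels, whole L4 larvae of strain OP436, synchronised by starvation at the L1 stage after bleaching and collected at 50 hours, were used, and chromatin was sheared by sonication before immunoprecipitation with an antibody against GFP. The 2 samples carry separate biological replicate numbers, were treated as biological replicates and form 1 group, so no condition was compared with another. The control library that the labels name was not analysed here.

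The authors deposited peak lists on the ce11 build, a ranked list and a thresholded list for each replicate and further lists made from both replicates, per the file list that came with the samples. The deposited score of each peak is the authors' irreproducible discovery rate (IDR) score, scaled to at most 1000, and the lowest score in the thresholded lists was 830 or, for replicate 1, 831. The deposited signal of each peak is the value that the authors' peak caller gave it, on a scale that the sources used here do not state. The aligner, the caller and their versions are not given in the sources used here. Read totals per library are not given there either, so the depth behind a peak is unknown and no value below has an interval that rests on it. Score and signal were used to rank, filter or describe peaks within a list, and the signal values of the replicates were related to each other by rank alone. The further columns of the ranked lists were not used here.

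The conservative thresholded list, made from the alignments of both replicates, served as the replicate-supported set, and the other whole-series list and each replicate's own list served as checks. A summit is the start of the peak plus its deposited offset. Background summits were the ranked summits of the same list whose score lay below the lowest score of the thresholded list. Genes and sequence came from the WBcel235 assembly with Ensembl release 115 and the RefSeq copy of WormBase WS298. Every peak end was checked to lie within the chromosome lengths of this assembly. Gene starts were the 5' ends of annotated transcripts, with piRNA genes left out.

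A gene was counted as bound when a transcript start lay within 500 bp of a summit, and its background was the genes with a start within 500 bp of any ranked summit. Shares were compared by two-sided Fisher's exact tests with 95% confidence intervals of the odds ratio, and Wilson 95% intervals were given for shares. These intervals cover counting error only. Peaks and genes are not replicates, so each p describes these lists. Benjamini-Hochberg adjustment was made within each family, namely 7 genomic classes, 10 biotypes, 29 gene lists, 11 preset motifs, all 8-mers tested, and the 6 chromosomes together with the chromosome centres. An exact p is that of Fisher's test throughout. An adjusted p below 0.05 was the threshold. Overlap of the replicates' lists was compared with 1000 circular shifts along each chromosome in a one-sided permutation test. The presence of 8-mers and motifs on either strand within 101 bp centred on the summit was compared by one-sided Fisher's exact tests with background windows matched on GC content in bins of 5 percentage points, 5 for each peak, for 8-mers present in at least 5 windows of the set. A tandem repeat was called where a 201 bp window matched itself at 75% identity or more at a shift of 5 to 80 bp. A peak was counted in a transgene region when its summit lay within 25 kb of madf-5 or unc-119, and the signal summed over each such region was ranked among 50 kb windows of the genome.

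The 29 gene lists were ribosomal proteins, translation factors, tRNA synthetases, spliceosome, proteasome, chaperones, respiratory chain, V-ATPase, histones, collagens, other cuticle and moulting genes, nuclear hormone receptors, homeobox genes, bHLH genes, the MADF family, neuropeptides and insulins, chemoreceptors, F-box and MATH genes, C-type lectins, detoxification enzymes, major sperm proteins, cell cycle and replication, DNA repair, synMuv and chromatin regulators, and markers of germline, muscle, intestine, neurons and epidermis. The genes named were those at the 25 peaks of highest signal, with starts within 500 bp or else the nearest start within 5 kb, up to 4 bound members of highest signal for each list past the threshold, and madf-5 and unc-119. The 10 8-mers of lowest p were named. Genes named outside this rule are said to be so where they appear.

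Alternatives covered the other whole-series list, each replicate's own list, the 50% of peaks with the highest signal, windows of 250 bp and 1000 bp around gene starts, windows of 61 bp and 201 bp around summits, flanking windows 300 bp away, other backgrounds, other definitions of overlap, and the transgene regions left out. Leaving out peaks at tRNA genes, a background of protein-coding genes, peaks put back into the list, tRNA genes on X and tRNA pseudogenes in each list, genomic classes among summits away from gene starts (6 classes, adjusted together), and 10 further draws of background windows were added later.

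The procedures were tested on simulated data. With no 8-mer planted, 0 of 4032 were called, and an 8-mer planted in 10% of 813 windows ranked 1 of 4026. With random bound genes among 25096, a gene list was called in 1 of 100 draws. With 20 ribosomal protein genes added, that list was called in 100 of 100 draws and another list in 3. Independent lists of 254 peaks gave an overlap p of 0.363, and 127 planted shared peaks were found as 128. Random summits gave a p of 0.733 for the share near gene starts. The random genes were drawn singly, whereas neighbouring genes can share a peak, and the simulated 8-mer windows were not matched on GC content. These checks therefore do not give the rate of false calls for the real lists. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with a fixed seed.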

Results

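The data describe the genomic sites of MADF-5, a protein with a MADF domain (a DNA-binding domain related to Myb/SANT), tagged with GFP and 3xFLAG and expressed from a fosmid transgene in L4 larvae. There were 2 biological replicates of 1 group. Replicate 1 had 411 thresholded peaks out of 64186 ranked peaks, and replicate 2 had 254 out of 70113. The replicate-supported set held 813 of 116935 ranked peaks, with a median width of 224 bp and a median signal value of 75.6. The other whole-series list held 844 peaks, and 644 of the 813 peaks (79.2%) stood in it at identical coordinates. Signal values are the authors' own and their scale is not stated.

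The strongest peaks of the replicate-supported set lay at a mixed group of sites, with protein-coding promoters, small RNA genes and repeats among them. The highest signal, 564 against the median of 75.6, fell at II 14561777-14561958, 245 bp from the start of mog-4 (WBGene00003392), which encodes a DEAH-box RNA helicase. This peak lies within 25 kb of madf-5, in a transgene region. The next highest, 261, lay at III 3867513-3867635, 309 bp from the start of rpl-3 (WBGene00004414), a large-subunit ribosomal protein gene. Of the 25 peaks of highest signal, 15 lay within 500 bp of a gene start, among them 5 at snoRNA genes and 3 at tRNA genes, and 5 lay in tandem repeats. All 25 were in the own thresholded lists of both replicates.

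Among protein-coding genes at these peaks, tasp-1 had a signal of 203 (III 10759136-10759359). The divergent pair F44E5.4 and F44E5.5, which encode Hsp70-family proteins, shared a peak of signal 196 at II 11759394-11759462. The ribosomal protein gene rpl-15 and its neighbour K11H12.8 shared a peak of 184 at IV 654817-655040. The gene for the HECT ubiquitin ligase eel-1 had 173 (IV 3050370-3050593), and the phosphoenolpyruvate carboxykinase gene pck-2 had 171 at I 7869026-7869128, in a tandem repeat. The snoRNA genes were C51F7.4 with C51F7.3 (signal 215, V 12303503-12303726), ZK994.7 (201.4, V 8500464-8500687), T06C12.16 (187, V 15873860-15874083), W03C9.9 (182, II 11960732-11960955) and T03F7.8 (162, V 11314106-11314329). The tRNA genes were WBGene00023110 with WBGene00023111 (174, X 3036028-3036251), WBGene00014275 (169.8, X 14063896-14064119) and WBGene00023062 (159, III 5305875-5305943). The ncRNA genes M02F4.12, C33G3.12, T03F7.14 and F52C9.10 also had starts within 500 bp of these tRNA or snoRNA peaks.

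The other 10 of these peaks had no gene start within 500 bp. Their nearest starts within 5 kb were those of C14C11.7 (signal 209), ccm-2 (207, in an intron), srv-14 (198, in a tandem repeat), WBGene00013722 (175), mdt-26 (164, in a coding exon), F09E5.7 (163), Y62F5A.12 (159.8) and fbxa-190 (159, in a tandem repeat). A pair of peaks at III 2499365-2499588 (signal 182) and III 2497873-2498096 (177) had no gene start within 5 kb, and both lay in tandem repeats.

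The replicates shared most of the shorter list. Of the 254 peaks of replicate 2, 165 (65.0%, Wilson 95% interval 58.9 to 70.6) overlapped a peak of replicate 1 by 1 bp or more. Circular shifts shared 0.441 peaks on average and 6 at most, and the one-sided permutation p of 0.000999 is the smallest that 1000 shifts can give. In the other direction, 163 of the 411 peaks of replicate 1 (39.7%, 35 to 44.5) overlapped replicate 2. Of the 813 peaks of the set, 162 stood in both replicates' own lists, 156 in that of replicate 1 alone, 67 in that of replicate 2 alone and 428 in neither. A ranked peak of both replicates lay within 100 bp of 767 of the 813 summits. Across these peaks, which are not independent, the Spearman correlation of the replicates' signal values was 0.407. Across the 953 of 5000 sampled background peaks with a ranked peak in both replicates it was 0.205. The set was chosen by the IDR score, which rests on agreement between replicates, so a higher correlation in it is partly built in.

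**Figure D1:**
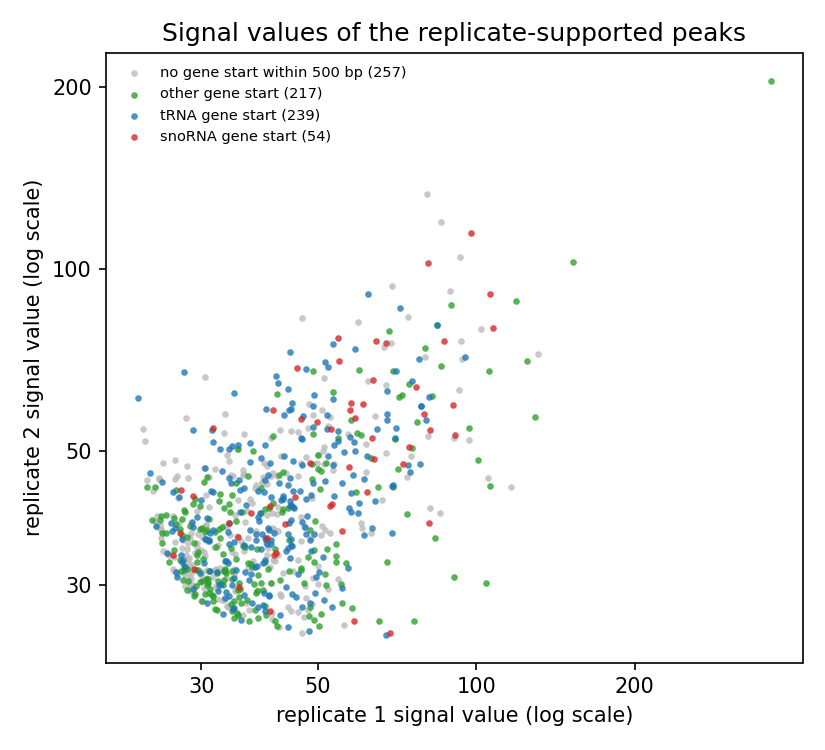
Signal values of the replicate-supported peaks in replicate 1 and replicate 2, both axes on a log scale, for the 767 peaks with a ranked peak in both. Points are single peaks coloured by the gene start within 500 bp, and the peak at mog-4 stands highest in both replicates.

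In the replicate-supported set, MADF-5 peaks lay mainly near gene starts, with distance counted alike on either side of a start. Of the 813 summits, 534 (65.7%, 62.4 to 68.9) lay within 500 bp of a gene start, against 31.6% of 115952 background summits (odds ratio 4.14, 95% interval 3.58 to 4.81, Fisher's exact p = 1.57e-87). The share was 69.8% in replicate 1 and 63.0% in replicate 2. It was 50.5% with peaks at tRNA genes left out (odds ratio 2.24, 1.895 to 2.66) and 55.5% with the ranked peaks past the threshold score but absent from the set put back (2.70, 2.38 to 3.08). Coding exons held 6.27% of the summits against 22.6% of the background (odds ratio 0.230, adjusted exact p = 9.16e-36; 0.134 in replicate 1 and 0.0653 in replicate 2), and introns held 6.89% against 22.5% (odds ratio 0.255, adjusted p = 1.85e-32). Intergenic sites held 17% against 19.2% (adjusted exact p = 0.189). These shares fall as that of gene starts rises, so the classes were also compared among the 279 summits away from gene starts, after the values were seen. There coding exons held 18.3% against 32.99% (odds ratio 0.454, 0.328 to 0.618) and introns 20.1% against 32.9% (0.513, 0.376 to 0.691), while intergenic sites held 49.5% against 28.1% (2.50, 1.96 to 3.19, adjusted exact p = 4.51e-13). The odds ratios in replicates 1 and 2 were 0.279 and 0.106 for coding exons, 0.442 and 0.584 for introns (not past the threshold in replicate 2, adjusted exact p = 0.0687), and 3.08 and 4.45 for intergenic sites. Away from gene starts, 3' UTRs held 6.81% against 3.28% (odds ratio 2.15, 1.27 to 3.44, adjusted exact p = 0.00513). Non-coding exons held 4.66% against 2.28% (2.09, 1.097 to 3.65, adjusted exact p = 0.0174). In replicates 1 and 2 the odds ratios were 2.96 and 1.63 for 3' UTRs and 2.28 and 2.36 for non-coding exons. Of these, only that of 3' UTRs in replicate 1 passed the threshold (adjusted exact p = 0.00217). Among all summits, the share in 3' UTRs was 2.34% against 2.25%, in non-coding exons 1.60% against 1.56%, and in 5' UTRs 0.246% against 0.310%, each with an adjusted p of 1. Circular shifts of the set placed 29.8% of summits near gene starts on average and 35.5% at most (two-sided permutation p = 0.002, the smallest that 1000 shifts can give).

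Genes for small structured RNAs stood out among the 960 bound genes. Of 568 tRNA genes, 288 (50.7%) were bound, against 3.83% of all 25096 background genes (odds ratio 36.5, 30.3 to 43.9, adjusted exact p = 5.75e-262). Of 315 snoRNA genes, which encode guides of RNA modification, 59 (18.7%) were bound (odds ratio 6.11, 4.49 to 8.20, adjusted exact p = 7.20e-24). Against the genes of all other biotypes, protein-coding genes were bound less often, 287 of 15720 or 1.83% (odds ratio 0.240, 0.208 to 0.277, adjusted exact p = 6.26e-97). So were pseudogenes, with 14 of 1503 (odds ratio 0.225, adjusted exact p = 7.24e-12). With peaks at tRNA genes left out these odds ratios were 0.697 (0.571 to 0.852, adjusted exact p = 0.00102) and 0.444 (0.227 to 0.787, adjusted p = 0.00628), closer to 1. Without replicate 1 they were 0.151 and 0.396, and without replicate 2 they were 0.252 and 0.292. In replicate 1 alone 148 tRNA genes (odds ratio 17.5, 14.03 to 21.8) and 47 snoRNA genes (7.96, 5.61 to 11.1) were bound. In replicate 2 alone these were 98 (20.1, 15.3 to 26.2) and 32 (10.3, 6.76 to 15.4), each past the threshold.

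Other RNA classes showed smaller differences. Of 105 snRNA genes, 11 were bound (odds ratio 2.96, 1.43 to 5.57, adjusted exact p = 0.00380), a call lost without replicate 1 (1.61, 0.191 to 6.07, adjusted p = 0.597) and with the 50% of peaks of highest signal (2.28, 0.722 to 5.54, adjusted p = 0.128). Of 6436 ncRNA genes, 292 were bound (odds ratio 1.28, adjusted exact p = 0.00138), and 197 of these had a tRNA gene start within 500 bp of their own start. The ncRNA call was lost without replicate 2 (odds ratio 1.15, 0.939 to 1.40, adjusted exact p = 0.236) and with peaks at tRNA genes left out (0.872, 0.685 to 1.102, adjusted p = 0.383). Binding of lincRNA genes (1 of 142, linc-44, adjusted exact p = 0.0665), miRNA genes (6 of 220, adjusted p = 0.603), antisense RNA genes (2 of 80, F17C11.20 and anr-5, adjusted p = 0.857) and rRNA genes (0 of 7, adjusted p = 1) did not pass the threshold, and the lincRNA and antisense RNA genes were named after their values were seen.

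**Figure D2:**
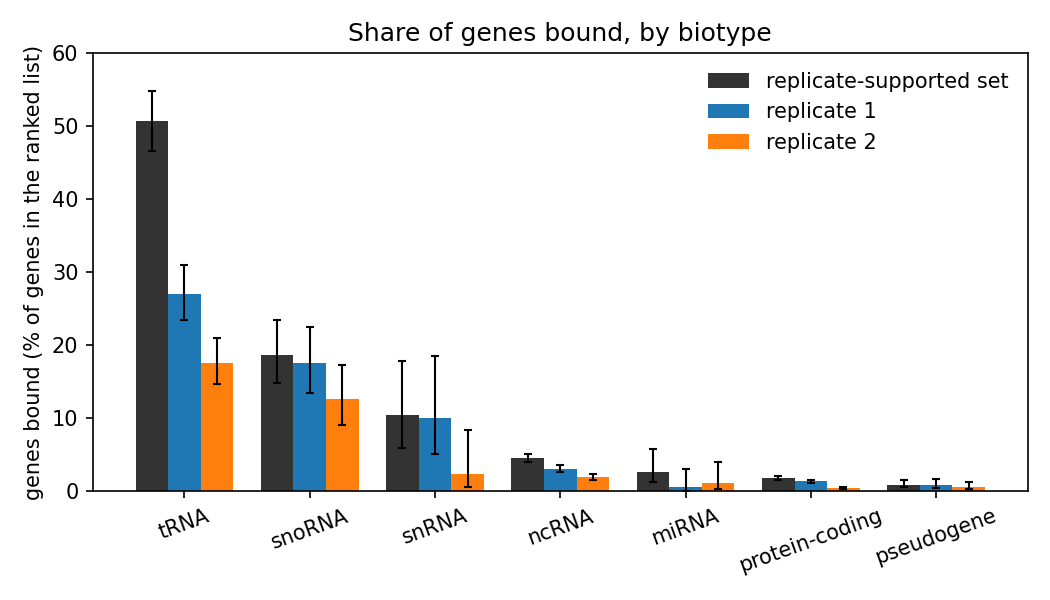
Share of the genes of each biotype that were bound (percent of genes in the ranked list) in the replicate-supported set, replicate 1 and replicate 2, with Wilson 95% intervals. In the set, 50.7% of tRNA genes and 18.7% of snoRNA genes were bound, against 1.83% of protein-coding genes.

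Binding reached tRNA genes of nearly every isotype. In the set, bound genes were found for 20 of 21 isotypes, the exception being the single tRNA-Sec gene, and in replicate 2's own list tRNA-Asn and tRNA-Met had 0 as well. The share was 67.7% for tRNA-Ala (21 of 31), 67.4% for tRNA-Lys (31 of 46), 66.7% for tRNA-Cys (8 of 12), 63.6% for tRNA-Trp (7 of 11) and 62.5% for tRNA-Gly (30 of 48), and it was lowest among the other isotypes for tRNA-His, with 2 of 15 (13.3%, 3.74 to 37.9). The 249 summits at tRNA genes lay a median of 23 bp downstream of the start, with an interquartile range of 4 to 44 bp, where the median tRNA gene is 72 bp long. Of 178 annotated tRNA pseudogenes in the background, 8 (4.49%, 2.29 to 8.62) were bound.

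The X chromosome carried 169 of the 813 summits (20.8%, 18.1 to 23.7), against 17.6% of the background (odds ratio 1.23, 1.03 to 1.46, Fisher's exact p = 0.0183). After adjustment over the chromosomes and chromosome centres this did not pass the threshold (adjusted exact p = 0.0640). It did in the other whole-series list (adjusted exact p = 0.00809), in replicate 1 (0.00428) and in replicate 2 (0.00939). Chromosome V carried fewer summits, 13.8% against 20.1% (odds ratio 0.636, 0.516 to 0.778, adjusted exact p = 2.57e-05), a call lost without replicate 1 (odds ratio 0.654, adjusted p = 0.0644). The direction on X reversed with peaks at tRNA genes left out, where 57 of 564 summits (10.1%, 7.88 to 12.9) lay on X against 17.4% of the background (odds ratio 0.532, 0.397 to 0.701, exact p = 1.49e-06). Without those peaks the share was 9.89% in replicate 1 (exact p = 0.00136) and 11.0% in replicate 2 (p = 0.0513). Of the 612 annotated tRNA genes, 276 (45.1%) are on X, and 112 of the 249 summits at tRNA genes were there. The share of tRNA genes bound was 51.5% on X and 50.0% on the autosomes (odds ratio 1.06, 0.754 to 1.5, exact p = 0.737). In each replicate's own list, examined after the values were seen, more were bound on X. The shares were 31.7% against 23.1% in replicate 1 (odds ratio 1.55, 1.04 to 2.31, exact p = 0.0263) and 20.7% against 15% in replicate 2 (1.48, 0.933 to 2.35, p = 0.0938). Of the summits at tRNA genes, 53.1% lay on X in replicate 1 against 41.3% of the background (exact p = 0.0211), and 54.3% against 40.3% in replicate 2 (p = 0.0218). Chromosome centres held 33% of summits against 32.6% of the background (adjusted exact p = 0.887), and no ranked peak lay on mitochondrial DNA (0).

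**Figure D3:**
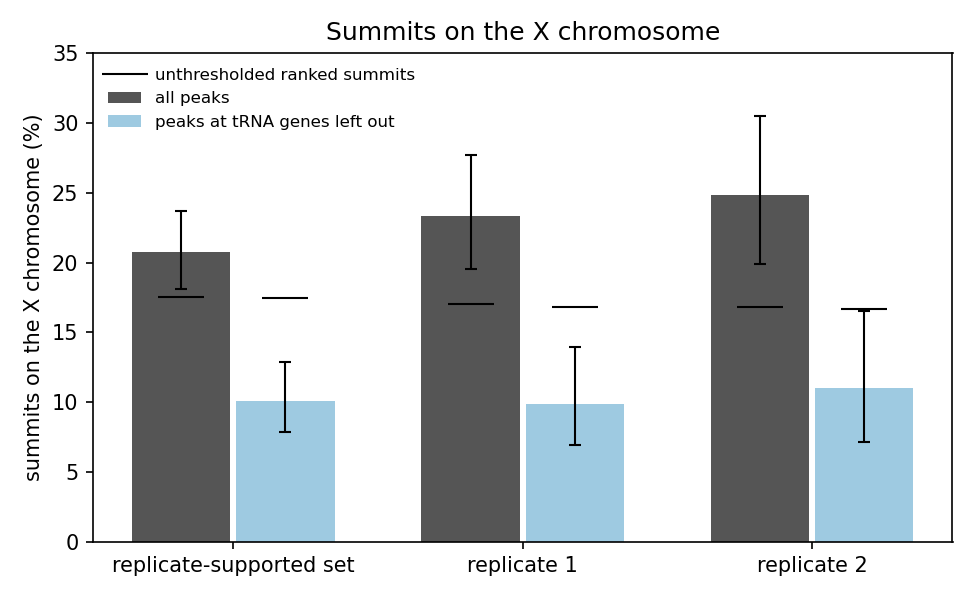
Share of summits on the X chromosome (percent) in the replicate-supported set and in each replicate, for all peaks and with peaks at tRNA genes left out, with Wilson 95% intervals. Lines mark the background summits, and in the set the share falls from 20.8% to 10.1% without the tRNA peaks.

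Ribosomal protein genes were the 1 gene list bound more often than other genes. Of 76, 20 were bound (26.3%, odds ratio 9.15, 5.18 to 15.6, adjusted exact p = 1.54e-10), led by rpl-3 (signal 261), rpl-15 (184), rpl-35 (157) and rpl-20 (154), all bound in both replicates' own lists. In all, 13 of these genes were bound in replicate 1 and 4 in replicate 2, and the call was lost without replicate 1 (odds ratio 4.19, 1.101 to 11.4, adjusted exact p = 0.267). Against protein-coding genes alone the odds ratio was 20.6 (11.5 to 35.4), and with the window of 250 bp it was 5.00 (2.14 to 10.4). Of the ribosomal protein genes with a snoRNA gene inside them or within 500 bp, 5 of 15 were bound, and of those without one 15 of 61 (two-sided Fisher's exact p = 0.522).

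Several large gene families were bound less often than other genes. Chemoreceptor genes had 3 of 873 bound, namely srh-269, srpr-2.2 and srpr-1.1 (odds ratio 0.0838, 0.0172 to 0.247, adjusted exact p = 2.32e-10), and the call stood in each alternative that was run. The list takes members by name, and srpr-2.2 and srpr-1.1 are ncRNA genes that encode the RNA of the signal recognition particle. Among protein-coding genes alone 1 of 868 was bound (odds ratio 0.0587, adjusted exact p = 3.81e-05). F-box and MATH genes had 0 of 291 (upper limit of the odds ratio 0.318, adjusted exact p = 0.000184), and 0 in each alternative. The call was lost without replicate 1 (upper limit 1.17, adjusted exact p = 0.774), without replicate 2 (0.794, adjusted p = 0.153) and with tRNA peaks left out (0.722, adjusted p = 0.0640). It was also lost against protein-coding genes alone with tRNA and snoRNA peaks left out (0.923, adjusted exact p = 0.174). Nuclear hormone receptors had 1 of 220 (nhr-41, signal 102, odds ratio 0.114, adjusted exact p = 0.0280) and C-type lectins 1 gene or 0.498% (clec-178, signal 37.5, odds ratio 0.125, adjusted p = 0.0472). Against protein-coding genes alone both of these calls were lost (odds ratios 0.243 and 0.266, adjusted exact p = 0.811 and 0.813). They were also lost without replicate 2 (adjusted exact p = 0.518 and 0.490) and without replicate 1 (1 for both), and that of nuclear hormone receptors in the other whole-series list (0.0800).

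Chaperone genes (5 of 49 bound, adjusted exact p = 0.160) and respiratory chain genes (4 of 40, adjusted p = 0.238) did not pass the threshold. Against protein-coding genes alone both did, with odds ratios of 6.20 (adjusted exact p = 0.0187) and 6.04 (adjusted p = 0.0418). Their bound members were dnj-28 (signal 135), dnj-13, hsp-90, hsp-16.2 and hsp-16.41 among chaperones, and atp-1 (103.9), cox-5A, cox-5B and cyc-2.1 in the respiratory chain. In replicate 1's own list 3 of each were bound (dnj-28, dnj-13 and hsp-90, and atp-1, cox-5A and cyc-2.1), and in that of replicate 2 there were 0 of either. The chaperone genes hsp-16.2 and hsp-16.41 share a single peak (signal 70.1), which the test counts once for each gene. Each of the other lists had an adjusted p of 0.160 or more. Bound members numbered 3 of 38 for the spliceosome (snr-1, uaf-1 and snr-4), 2 of 130 for collagens (col-85 and col-54), 2 of 131 for detoxification enzymes (gst-27 and gst-9) and 2 of 59 for cell cycle and replication (cdc-48.1 and mcm-4). A single gene was bound in V-ATPase (1 of 20), other cuticle and moulting genes (1 of 61), homeobox genes (1 of 51), major sperm proteins (1 of 31), synMuv and chromatin regulators (1 of 34), translation factors (1 of 35), germline markers (1 of 46) and intestine markers (1 of 28). These were vha-2, nas-10, ceh-43, msp-33, lin-54, iff-2, ego-1 and vit-2, and the members of the lists in this paragraph were named after their values were seen. The signal of lin-54 (77.2) equals that of rpl-12, and that of snr-4 (62.1) equals that of the snRNA gene WBGene00014291, as a shared peak would give. The genes rpl-12 and WBGene00014291 were likewise named after the values were seen. None was bound among neuropeptides and insulins (0 of 108), neuronal markers (0 of 37), histones (0 of 36), proteasome (0 of 32), muscle markers (0 of 30), tRNA synthetases (0 of 29), DNA repair (0 of 25), epidermis markers (0 of 20), bHLH genes (0 of 16) and the MADF family (0 of 8).

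The sequences most enriched under the summits were those of tRNA genes. Of 3836 8-mers tested, 1240 passed the threshold, and all of the top 10 occur in annotated tRNA genes. The 8-mer AGTGGTTA was present in 72 of 813 windows (8.86%) and in 0.295% of 4065 windows matched on GC content (adjusted exact p = 3.72e-41), and GGGTTCGA in 9.59% against 0.590% (adjusted p = 4.19e-38). The remaining top 8-mers were CTGAGCTA (8.61% against 0.517%), GCTCTACC (7.01% against 0.197%), ACTGAGCT (7.75% against 0.517%), ATTGAACC (6.15% against 0.344%), CGCTCTAC (5.17% against 0.221%), ATCGAACC (6.27% against 0.566%), AACCACTA (5.17% against 0.320%) and CTAGACCA (3.81% against 0.0492%). Without replicate 1 the count was 445. With peaks at tRNA genes left out 374 8-mers passed, led by CACTCGGC, present in 25 windows (4.43% against 0.142%, adjusted exact p = 4.93e-13). ACCACTCG and CCACTCGG, which overlap it, passed as well. So did AGTGGTTA (4.08% against 0.177%, adjusted exact p = 1.67e-11) and ATTGAACC (3.19% against 0.319%, adjusted p = 1.04e-06). Both are named above among the 8-mers that occur in annotated tRNA genes. Read on the other strand, AGTGGTTA overlaps ACCACTCG. In the whole set CACTCGGC was present in 36 windows and ACCACTCG in 44, against 25 and 24 without the peaks at tRNA genes. CACTCGGC is therefore not shown to be separate from tRNA sequence.

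Among the preset motifs, GGTTCGA, the core of the tRNA B box, was present at 17% of summits against 1.94% (odds ratio 10.3, 7.66 to 13.9, adjusted exact p = 2.61e-56). In 10 other draws of the background its odds ratio lay between 11.7 and 15.2, and with peaks at tRNA genes left out it was 3.77 (2.23 to 6.29, adjusted exact p = 2.36e-06). Without replicate 1 it was 18.01 (9.98 to 34.0), and without replicate 2 it was 11.5. GCGCGC was present at 4.55% against 2.34% (odds ratio 1.99, 1.31 to 2.97, adjusted exact p = 0.00343), a call lost without replicate 1 at a similar odds ratio (1.87, 0.969 to 3.45, adjusted p = 0.171), and with peaks at tRNA genes left out its odds ratio was 3.36 (2.13 to 5.26). GAGAGA was present at 10.6% against 8.12% (adjusted exact p = 0.0538), and it passed the threshold in 6 of the 10 other draws. It also passed in the wider window around summits (odds ratio 1.57, adjusted exact p = 1.13e-05), against flanking windows (1.97, adjusted p = 3.36e-05), in the other whole-series list (1.33, adjusted p = 0.0478) and with transgene regions left out (1.38, adjusted p = 0.0310). GAGAGA did not pass without replicate 1 (1.17, adjusted exact p = 0.763) or without replicate 2 (1.41, adjusted p = 0.109). Nor did it with the 50% of peaks of highest signal (1.43, adjusted exact p = 0.0936) or with tRNA peaks left out (1.23, adjusted p = 0.376). For GGGCGG, the E2F-like patterns, the GATA motif TGATAA, CACGTG, TGACGTCA, CTGCGTCT, TTTCAG and AAAAAA the adjusted p was 0.539 or more. Other windows and backgrounds called some of them. GGGCGG passed in the wider window around summits (odds ratio 1.44, adjusted exact p = 0.0123) and against flanking windows (4.08, adjusted p = 7.36e-08), and CACGTG against flanking windows (1.87, adjusted p = 0.0464). AAAAAA was more frequent in the wider window (1.56, adjusted exact p = 2.73e-08) and, in a direction tested after the values were seen, less frequent against flanking windows (0.326, adjusted p = 1.54e-27). In the opposite direction, tested after the values were seen, TTTCAG was less frequent (7.75% against 12.0%, one-sided adjusted exact p = 0.00181), and not past the threshold with tRNA peaks left out (10.6% against 12.6%, adjusted p = 0.420). Also in that direction, TGATAA was less frequent against flanking windows (odds ratio 0.607, adjusted exact p = 0.0102) and TGACGTCA in the wider window (0.286, adjusted p = 0.0204).

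The strain carries a fosmid transgene of madf-5 and an unc-119 gene that rescues its unc-119 mutation, and of these regions only that of madf-5 stood out. Within 25 kb of madf-5 (II 14550088-14600088), 5 set summits and 60 ranked summits were found. Each replicate's own list held 2, the peak at mog-4 being in both, and 2 of the 5 set summits were in neither. The signal summed there was 1.83 times that of the median window and lay in the top 0.400% of 4001 windows, with 0.200% in replicate 1 and 0.400% in replicate 2. The peak at mog-4 had the highest signal, with 363 in replicate 1 and 205 in replicate 2. The other 4 lay at the pseudogene WBGene00044053 (signal 70.5, II 14563854-14564077), at II 14570712-14570935 (91.2) and II 14572332-14572555 (64.4) between genes, and in a coding exon within madf-5 (82.9, II 14574879-14575102). The start of madf-5 itself (WBGene00007242) had no ranked summit within 500 bp. Of the 4001 windows, 13 held 5 or more set summits. Within 25 kb of unc-119 (III 10880788-10930788) there were 0 set summits and 49 ranked summits, and the summed signal lay in the top 59.0% of windows in replicate 1 and the top 72.9% in replicate 2.

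**Figure D4:**
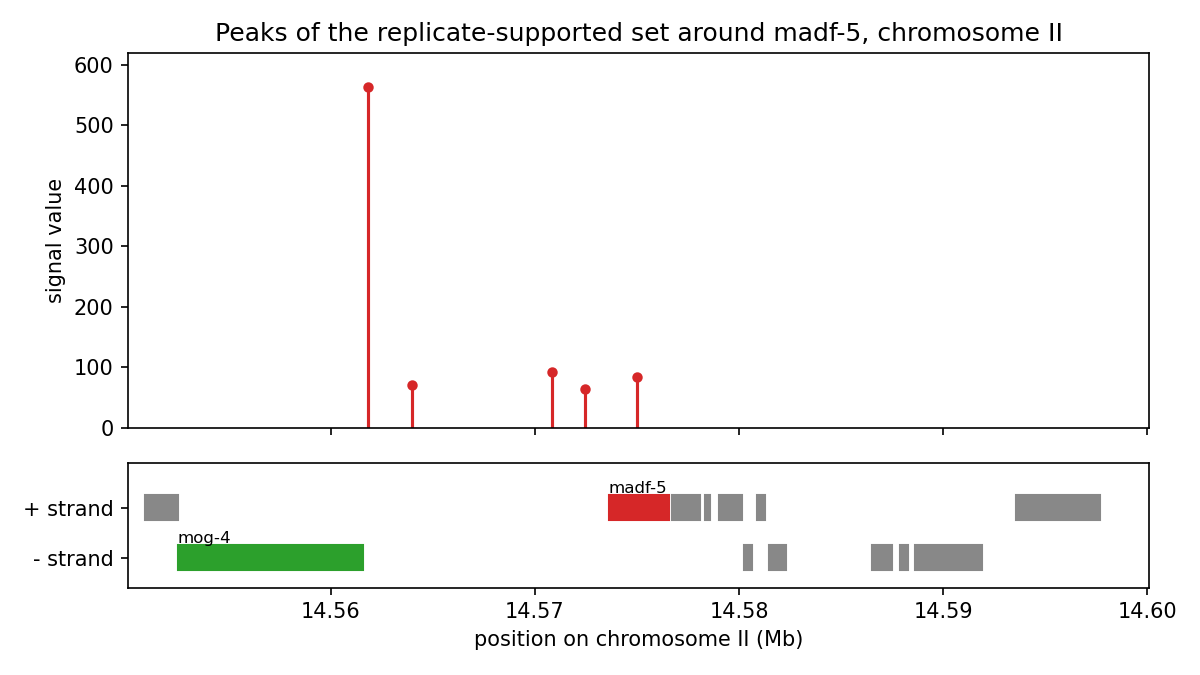
Peaks of the replicate-supported set within 25 kb of madf-5 on chromosome II, placed by summit position (Mb) with signal value as height, above the annotated protein-coding genes on each strand. The peak beside mog-4 reaches a signal of 564, and the other 4 lie between 64.4 and 91.2.

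Peaks at gene starts fell on divergent promoters, where a pair of protein-coding genes point apart, more often than the background did. Of 534 such summits, 30 (5.62%, 3.96 to 7.91) had both starts within 500 bp, against 2.99% of 36644 background summits (odds ratio 1.93, 1.29 to 2.81, Fisher's exact p = 0.00127). Examples among the strongest peaks are F44E5.4 with F44E5.5 and rpl-15 with K11H12.8. Without replicate 1 the difference was not past the threshold (6 of 160 summits, 3.75%, odds ratio 1.37, 0.495 to 3.08, exact p = 0.460), and in replicate 1 alone the share was 8.01% (p = 3.74e-05). With peaks at tRNA genes left out the share was 10.2% against 3.03% (exact p = 2.29e-08).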

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

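The tests of identical tRNA copies and of extra copies at both transgene regions were set before their results were seen, and the other tests in this part were chosen only after the result was seen. The ranked list held 170 peaks past the threshold score that were absent from the replicate-supported list (17.3% of 983), a signal in data outside the comparisons above. Their highest signal value was 3573 at X 15810959-15811186, against 564 in the replicate-supported set. Of these peaks, 158 lay away from gene starts and 123 lay in tandem repeats, and they made up 48 of the 50 ranked peaks of highest signal. The file list names an additional parent file for the thresholded lists without describing it.

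Binding at tRNA genes had the largest odds ratio of the biotypes. GC content was argued against as the whole cause, since against background summits matched on GC content the odds ratio of a tRNA gene start within 500 bp was 55.6 (95% interval 37.9 to 83.9). Reads shared between identical copies were argued against as the whole cause as well. Of the 127 tRNA genes whose sequence is found at a single place, 38.6% (30.6 to 47.3) were bound, against 1.83% of protein-coding genes. This share is lower than the 50.7% of all 568 tRNA genes, as a partial contribution from identical copies would give. Whole gene sequences were compared, so reads shared between nearly identical copies were not excluded, nor was a partial contribution from identical ones. Recovery of any strongly transcribed gene cannot be told apart from specific binding, because 1.32% (0.450 to 3.81) of muscle, histone, collagen and major sperm protein genes were bound, an interval that spans the share of protein-coding genes, while ribosomal protein genes at 26.3% would go with it. The odds of binding at tRNA pseudogenes were 0.0459 times those at tRNA genes (0.136 in replicate 1, 0.208 in replicate 2). Lower odds were the prediction for occupancy of annotated tRNA genes rather than of tRNA-like sequence. How far the pseudogenes keep tRNA sequence was not examined, so the test does not separate these readings. GGTTCGA or GGTTCAA was also enriched at peaks away from gene starts (odds ratio 5.26). With 1 group, no other biological explanation was tested.

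The cluster of peaks around madf-5 surrounds the gene that the fosmid transgene carries. Extra copies at both transgene regions were argued against, since unc-119 had no set summit and a summed signal no higher than the top 59.0% of windows in either replicate, although a rescuing copy from another species, which the labels neither state nor exclude, would add no reads there. Extra copies of the madf-5 region alone remain a candidate explanation, since the median signal of the unthresholded summits there lay in the top 4.74% of windows in replicate 1 and the top 0.376% in replicate 2. The peak at mog-4 rises far above its neighbours in the same region, with 564 against 64.4 to 91.2, and whether copies account for that difference was not tested. No biological explanation was tested for this pattern.

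Away from gene starts, tandem repeats held 34 of 279 set summits (12.2%) against 1.06% of the background (odds ratio 12.9, 8.70 to 18.7), and 153 of 437 once the peaks missing from the list were put back. Reads of repeat copies collapsed onto the reference remain a candidate explanation, since with those peaks counted repeats without a heat shock element passed the threshold score more often than sites outside repeats (odds ratio 48.2, 38.6 to 60.01). Repeats with the element stood in the list more often than repeats without it (odds ratio 7.38, 3.07 to 16.8), but with the missing peaks counted the interval spans 1 (1.68, 0.855 to 3.15), so this does not argue against collapsed reads. Recognition of heat shock elements was left open, because outside repeats the element was at 4 of 774 set summits and 14 of 3870 matched ones (odds ratio 1.43, 0.342 to 4.57). No other biological explanation was tested for this pattern.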

How the results depend on the processing

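The replicate-supported set, the gene lists, the motifs and most alternatives were chosen before the data were examined. Leaving out peaks at tRNA genes, backgrounds of protein-coding genes, peaks put back, other draws of background windows, and all alternatives for genomic class, tRNA genes on X, tRNA pseudogenes, tandem repeats and the transgene regions were chosen only after the result was seen. Over 228 recomputed values, 67 of those that answer a comparison were counted as unchanged, 25 moved, 1 lost its threshold and 1 reversed. Counts were unchanged when they stayed near the reported count. Shares were unchanged when they kept their direction and side of the threshold, whatever their size. The shares in tandem repeats and at divergent promoters rose in some alternatives counted as unchanged. The gene start share stayed past its threshold in all 11 alternatives, and the overlap of replicates in all 3, from 52.8% with equal numbers to 63.8%. The reversal was the share of summits on X, 10.1% with peaks at tRNA genes left out, and 45.1% of tRNA genes lie on X.

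Leaving out each replicate in turn gave 254 to 411 peaks, 445 to 960 8-mers, 1 to 2 preset motifs, 0 to 1 gene lists bound more often, 1 to 1 lists bound less often, a divergent share of 3.75% to 8.01% and a madf-5 region in the top 0.200% to 0.400% of windows. Each replicate's own list holds fewer peaks. By construction, the 50% of peaks with the highest signal gave 406 peaks. With peaks at tRNA genes left out there were 374 8-mers of fewer tested (1810 against 3836). Gene lists bound more often numbered 2 with the other whole-series thresholded list (respiratory chain added), 2 with the window of 1000 bp (chaperones added), and 3 with peaks at tRNA genes left out, 3 with protein-coding genes alone as background and 3 with peaks at tRNA and snoRNA genes also left out (chaperones and respiratory chain added in each). Lists bound less often, 4 as reported, numbered 2 with the 50% of peaks of highest signal, 2 with the window of 250 bp, 2 with each peak given to its nearest start, 2 with protein-coding genes alone as background, 1 with peaks at tRNA genes left out and 1 with protein-coding genes alone and peaks at tRNA and snoRNA genes left out. Biotypes bound more often, 4 as reported, numbered 2 with peaks at tRNA genes left out, where tRNA genes drop out by construction and ncRNA genes lost the call. The odds ratios of those that stayed rose to 14.8 for snoRNA genes and 6.19 for snRNA genes. Their bound shares did not rise, as with 18.4% of snoRNA genes against 18.7% as reported, while the share of all genes fell. Genomic classes past the threshold numbered 5 with summits away from gene starts alone. Preset motifs past the threshold numbered 5 with the wider window around summits and 5 with flanking windows as background. The cause of these changes in lists and motifs was not tested.

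Of the odds ratios of single groups and motifs, most alternative values kept their side of the threshold, 2 reversed with peaks at tRNA genes left out without passing it (ncRNA genes 0.872, miRNA genes 1.35), 1 passed it where the reported value had not (tRNA genes on X against the autosomes without replicate 2), and 27 kept their direction without passing it. The latter were 9 for C-type lectins, 9 for nuclear hormone receptors, 4 for F-box and MATH genes, 2 for snRNA genes, and 1 each for ncRNA genes, GCGCGC and ribosomal proteins. Ribosomal proteins lost the call without replicate 1 (odds ratio 4.19). The read depth of the libraries is not given in the sources used here, so its effect on the shorter list of replicate 2 could not be measured.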

Other observations

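The genes and tests in this part were chosen only after the result was seen. The RNA genes of the ribonucleoprotein enzymes RNase P and RNase MRP were bound. The RNase P gene rpr-1 (WBGene00045238, I 13463955-13464207) had a peak of signal 127, and it was bound in both replicates' own lists. The RNase MRP gene mrpr-1 (WBGene00045095, II 7200233-7200418) had a peak of 87.1, and it was bound in that of replicate 1 alone. Among the srpr genes, which encode the RNA of the signal recognition particle, srpr-2.2 (81.1) and srpr-1.1 (71.8) were bound, and srpr-1.2, srpr-2.1 and srpr-3 were not, although srpr-2.1 was bound in replicate 2's own list. The Y RNA gene yrn-1 was in the background and was not bound. Among the snRNA genes, 3 of 18 that hold a short stretch of U6 sequence were bound (WBGene00014543, WBGene00014266 and WBGene00235247). So were 3 of 17 sls-2 genes, which encode trans-splicing leader RNAs (sls-2.9, sls-2.4 and sls-2.8). None of 3 sls-1 genes was bound. The highest signals were 133.0 at sup-6, 130.4 at WBGene00014543 and 95.3 at sls-2.9.

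Of 13 heat shock genes examined, 6 of the 9 in the background were bound, and the other 4, copies of hsp-16.1 and hsp-16.48, had no ranked summit within 500 bp of a start. These genes were picked with their binding known, so 6 of 9 does not measure how often heat shock genes were bound. In the chaperone list, set before the data were examined, 5 of 49 were bound, which did not pass the threshold (adjusted exact p = 0.160). Beside F44E5.4 and F44E5.5 (signal 196), dnj-13 had 114, hsp-90 had 91.4, and the divergent pair hsp-16.2 and hsp-16.41 shared a peak of 70.1 at V 1805091-1805314. F44E5.4 and F44E5.5, which also share a peak, were bound in both replicates' own lists, dnj-13 and hsp-90 in that of replicate 1 alone, and the hsp-16 pair in neither. A heat shock element (3 alternating GAA and TTC units spaced by 2 bp) lay in the sequence window of 4 set summits outside tandem repeats, those of F44E5.4 with F44E5.5, hsp-16.41 with hsp-16.2, the tRNA gene WBGene00010733 and syx-18. No peak of the set lay at the starts of hsp-70, hsp-1 or hsp-110.

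Some peaks away from gene starts carried tRNA-like sequence. GGTTCGA or GGTTCAA was present at 29 of 279 such summits (10.4%) and at 2.15% of matched background summits away from gene starts (odds ratio 5.26, 2.99 to 9.25, p = 3.86e-09, Fisher's exact test). Of the 279 summits, 245 lay outside tandem repeats, with a median signal of 69.2 and a highest of 209. The 11 in repeats with a heat shock element had a median of 81.9, and the 23 in repeats without one had 88.7.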
